A study of Mus musculus with 15 samples.

How the data were processed

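Gene expression was measured by RNA sequencing of whole testes from C57/BL6 mice. The 15 libraries fall into 5 groups of 3, named Control, MTX, HMS-I1, AA and TSA in the labels, which spell out none of the treatment abbreviations and give no dose, age or duration. Per the labels' protocols, RNA was extracted with Trizol, purified on columns, made into libraries with an Illumina RNA kit and sequenced on a NovaSeq instrument. The libraries were grouped by their titles. For HMS-I1 the titles name 3 replicates of HMS-I1, while the treatment field reads HMS-I1, HMS-I2 and HMS-I3. The labels do not settle whether these are replicates of a single treatment, and every HMS-I1 value and its n of 3 rests on the titles. Nothing in the labels says that the replicates are separate animals, so the p-values measure only the spread between these samples, which may be technical.

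The deposited values are a signal table of normalised counts, with 36118 Ensembl gene identifiers and 1 column per library. Per the submitters' processing notes, the tools were FastQC 0.11.9, Salmon 0.12.0 and DESeq2 1.34.0, with the genome build GRCm39. Salmon estimates how many reads belong to each transcript, so the values are not whole numbers even before scaling. Whole reads could not be recovered from them, and the depth of each library is unknown. The column sums of the deposited signal, 2.75e+07 to 4.06e+07, are not depths, and no counting interval is given for any value. The strand setting of the counting is not given in the sources used here. Of the identifiers, 35825 were matched by their Ensembl number to a symbol in an annotation of the earlier build GRCm38, and 293 were not. That annotation was used for names, gene types and transcript sequences only, and no coordinates are given because the builds differ. Its symbols are older in places, so the histone genes carry names such as Hist1h1c and H2afx.

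All values were analysed as log2(normalised count + 1), which understates the fold change of genes near 0. The 17896 genes with a mean of at least 10 over the 15 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on the mean). A single model held the means of the 5 groups, with 10 residual degrees of freedom. The tests of genes and lists were two-sided, and p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. The comparisons were each of the 4 treatments against Control, the 6 pairs of treatments, and an F-test of any difference among the 5 groups. Fold changes are differences of mean log2 values with their standard error (SE) from the model. SD is the standard deviation over the 3 libraries of a group.

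A set of 31 gene lists was fixed before the data were examined. They cover testis cell types, meiotic functions, histones and histone-modifying enzymes, stress and metabolic pathways, and cell types from outside the seminiferous tubules. Each list was tested against all other genes with camera at a preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry for a change of its members as a set. These p-values were adjusted over the 31 lists of a comparison. Counts of members past the threshold were made with p-values adjusted over all genes and adjusted over the list alone.

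The genes named in the text were also set by a rule fixed before the data were examined. It takes the 10 largest changes in each direction among genes past the threshold, members of the lists past the threshold, and genes past the threshold in all 4 treatments. Where fewer than 10 genes passed, it takes the 5 higher and the 5 lower genes with the smallest p, a mean of at least 50 and a proper symbol, which are then said not to pass. Where no member of a list passed, it takes up to 2 members with the smallest p and gives their values. Not every gene that the rule picks is reported here. Genes named outside the rule are marked as chosen after their values were seen.

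The tests were tried first on simulated data with known changes in genes with the means and spreads of these libraries, over 17896 genes. For MTX against Control, the test found 14.9% of genes changed by 1 on the log2 scale, 44.8% of those changed by 2 and 93.9% of those changed by 4. For TSA against Control the shares were 8.96%, 53.7% and 86.4%, for AA 7.46%, 46.3% and 90.9%, and for HMS-I1 16.4%, 62.7% and 84.8%. These simulations held no library sets. With the sets kept, the shares at 1 were 10.4% for MTX, 11.9% for HMS-I1, 2.99% for AA and 4.48% for TSA, and with the set as a term as well 31.3%, 34.3%, 20.9% and 20.9%. The 4 simulated comparisons had the same means, spreads and layout, so their shares differ by the random draw and not by treatment. The spread was drawn independently for each gene and library, with no structure beyond the library sets. Changes in the real libraries may therefore be found less often than these shares. A list shifted as a whole was called in each simulated comparison, with 0 of the 30 other lists called. The genes of that simulation were independent of each other and held no library sets. It therefore says nothing on false calls among lists of correlated genes.

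The first principal component of the tested genes separated 6 libraries from the other 9, without following the groups. This split is not in the labels and was found in the data. It is called the first and the second set, and the gene counts and list results were also computed with the set as a term in the model (9 residual degrees of freedom) and within each set. The similarity of the treatments was computed with the set term but not within the sets. These alternatives, and leaving out a library together with the set term, were chosen after seeing the data. The alternatives fixed before were other pseudocounts (0.5 and 5), other filters, other scalings, other variance models, array quality weights, a fold threshold, a replicate block, fits of only the groups compared, and leaving out each library in turn. A count test was not run because the deposited values are not counts. Words of 31 bases in the transcripts of the annotation were used to measure how much of each gene's sequence is shared with another gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.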

Results

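Whole testes of C57/BL6 mice were profiled by RNA sequencing in a control group and under 4 treatments, MTX, HMS-I1, AA and TSA, with 3 libraries in each group. The series concerns modifications of histones and the organisation of chromosomes in the prophase of meiosis. A whole testis holds spermatogonia, meiotic spermatocytes, haploid spermatids and the somatic Sertoli, Leydig, myoid, vessel and immune cells, so its profile mixes all of these. The deposited values are normalised counts that sum to 2.75e+07 to 4.06e+07 per library, and the sequencing depth is unknown. Libraries had 20683 to 22858 genes above 0. Within a group, the correlation of log2 values between libraries was 0.829 to 0.966 across genes, and 0 pairs of libraries were identical.

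The strongest contrast in the data lay between libraries of the same group. Control replicates 1 and 2 and replicate 1 of each treatment, 6 libraries called the first set here, held very high values of histone genes and low values of mitochondrial genes. Control replicate 3 and replicates 2 and 3 of each treatment, the 9 libraries of the second set, showed the opposite. A group of 60 histone genes was picked by their Hist names and is called replication-dependent here. It also holds histones of germ cells, such as Hist1h1t and Hist1h2ba. The mean log2 value of these 60 genes was 7.79 to 8.82 in each library of the first set and 2.95 to 3.86 in the second. Ccnb1ip1 (ENSMUSG00000071470), a regulator of meiotic crossing over, was listed at 222044 to 448329 normalised counts in the first set and at 124 to 467 in the second. The linker histone of spermatocytes, Hist1h1t, was at 15472 to 20960 against 47.4 to 147. The 13 mitochondrially encoded genes made up 1.08% to 1.40% of a library's total in the first set and 3.54% to 13.7% in the second. Several lists of somatic cells were lower in the first set, with a median log2 difference of -1.12 for peritubular myoid cells, -0.82 for macrophages and other leukocytes and -0.67 for Sertoli cells. Adipocyte genes (0.50, 6 of 9 higher) and Epididymis genes (1.09, 4 of 4 higher) went the other way. Spermatogonia genes differed by -0.85 and extracellular matrix genes by -1.06, while Round spermatids (0.40) and Elongating spermatids (0.39) were higher. The first principal component, with 50.5% of the variance, ran from -96.3 to -77.6 in the first set and from 29.8 to 116 in the second. The second set was itself uneven on the second component (14.8%). Replicate 3 of MTX, HMS-I1 and TSA lay there at 39.3, 65.7 and 83.7, and replicate 2 at -91.0, -40.8 and -7.34. Control replicate 3 lay at -41.9, and AA replicates 2 and 3 at 7.43 and -1.28. Medians within the second set thus compare unlike libraries with a single control. The sets were drawn from these same values, so no test of their difference is given. Each treatment has 1 library in the first set and 2 in the second, and Control has 2 and 1.

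**Figure D1:**
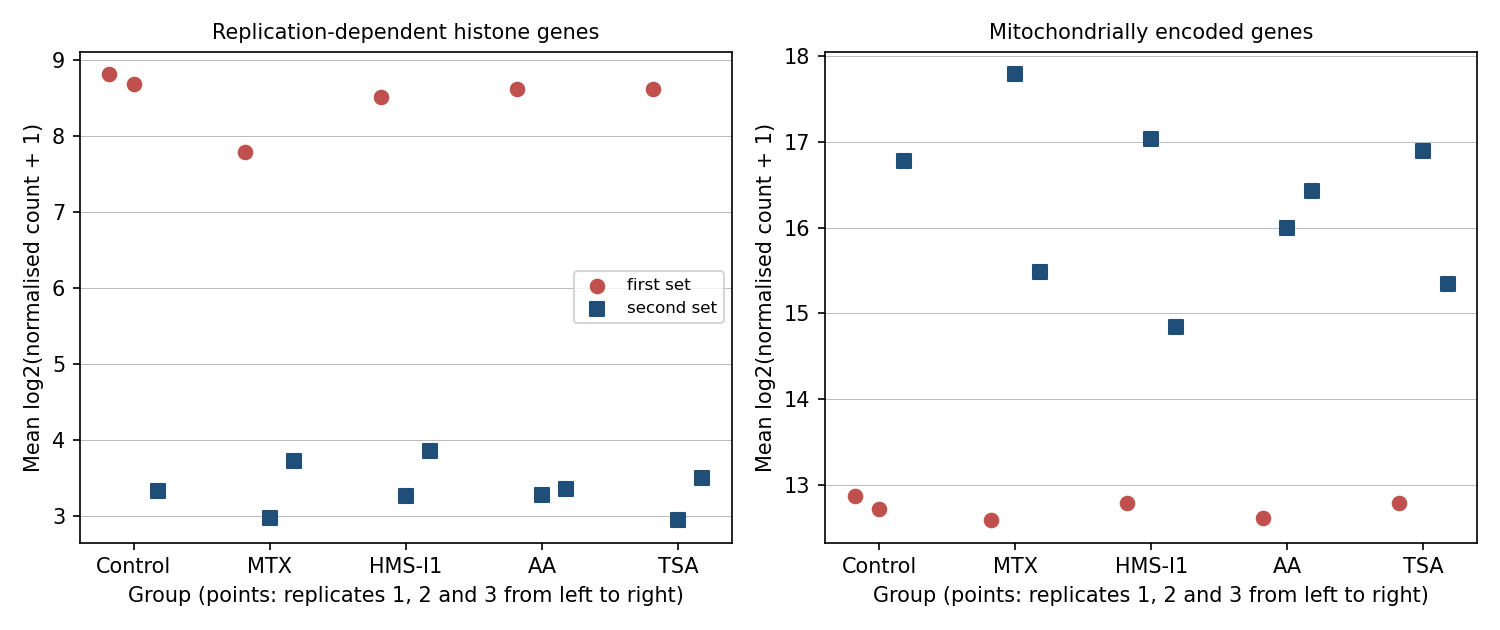
Mean log2(normalised count + 1) of 60 histone genes (left) and the 13 mitochondrially encoded genes (right) in each of the 15 libraries, by group. The histone genes were picked by name and are called replication-dependent. There is 1 point per library and no error bar. Circles mark the 6 libraries of the first set, at 7.79 to 8.82 for the histone genes, and squares the 9 of the second set, at 2.95 to 3.86.

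In MTX against Control, no gene passed the threshold, and the gene lists that stood out were uneven between libraries. Interferon response genes, which cells raise on viral or immune signals, lay higher in MTX in 15 of 20 members, with a median log2 fold change of 0.31 (camera adjusted p = 0.00250). The 13 mitochondrially encoded genes were all higher, by a median of 1.12 (camera adjusted p = 0.00250). Macrophage and leukocyte genes were higher in 19 of 21 members (median 0.35), the 5 Erythroid genes in 5 of 5 (median 0.69), and Linker and variant histones were lower in 14 of 20 (median -0.56). Each of these 5 calls was lost with an estimated correlation (adjusted p = 0.977 for each), and fry called 0 lists. Meiotic chromosome axis and synapsis genes, 26 in number, had a median of 0.06 with 14 members higher (camera adjusted p = 0.844, and 0.977 with an estimated correlation).

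Single members of these lists did not pass either. Zbp1, a sensor of foreign nucleic acid, was 1.88 higher (SE 0.98), with an adjusted p of 1 (limma). Csf1r, a macrophage receptor, was at -0.91 (SE 0.49), opposite to its list, and H2-Ab1, an antigen-presenting molecule, at 0.97 (SE 0.57). The haemoglobin genes Hbb-bs and Hba-a2 were at 0.83 (SE 0.68) and 1.00 (SE 0.83). H2afx, the histone variant of DNA damage signalling, was at -0.39 (SE 0.24). Ldhc, the lactate dehydrogenase of germ cells, was at 0.42 (SE 0.23), Tnp2, a transition protein of condensing spermatids, at -0.69 (SE 0.43), and the deacetylase Hdac8 at 1.01 (SE 0.46). Of the genes with the smallest p, the 5 higher were Rsad1, Mkks, Nme7, Psma3 and Rnf182 and the 5 lower Vangl1, Trim6, Zfp536, Pcnx3 and Smpd4, and 0 of the 10 passed. Rsad1 (ENSMUSG00000039096) stood at 124 ± 9.38 normalised counts in MTX and 62.4 ± 12.7 in Control (SD, n = 3 each), a difference of 0.99 (SE 0.28). Vangl1, a planar cell polarity protein, stood at 34.5 ± 18.3 against 96.2 ± 15.1, a difference of -1.62 (SE 0.50).

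Over all 17896 genes, limma called 0 in MTX against Control, and 98 had an unadjusted p under 0.05, where 894.8 are expected by chance. Such a shortfall means that the p-values ran high, so 0 calls are no evidence that nothing changed. Without the filter on the mean, each of the 5 list calls was lost. With the library set as a term limma also called 0 genes, with 328 at an unadjusted p under 0.05. None of the 5 list calls was kept then. Camera instead called 4 other lists, with Spermatogonia (-0.17), Sertoli cells (-0.19) and Endothelium (-0.28) lower and Cytosolic ribosomal proteins (0.11) higher, and 0 with an estimated correlation (smallest adjusted p = 0.430). With the set and a replicate block together, the Interferon call passed (median 0.44, camera adjusted p = 0.00462). The mitochondrial median was -0.19 within the first set and -0.07 within the second, and the call was also lost without Control replicate 1 (0.45), Control replicate 2 (0.53), MTX replicate 3 (1.09) or MTX replicate 2 (-0.21). The interferon median was -0.35 in the first set and 0.81 in the second, and the call was lost without MTX replicate 3 (-0.02) or Control replicate 3 (0.28). The Erythroid median was 0.41 in the first set and 0.17 in the second, and the call was lost without MTX replicate 3 (-0.08) or Control replicate 1 (0.35). The Macrophage median was near 0 in the first set (-0.00499) and 0.33 in the second, with the call lost without Control replicate 2 (0.20), Control replicate 3 (0.36) or MTX replicate 3 (0.11). Linker and variant histones were at -0.16 and -0.03, with the call lost without Control replicate 1 (-0.33), Control replicate 2 (-0.49), MTX replicate 2 (-0.31) or MTX replicate 3 (-0.56).

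In HMS-I1 against Control, no gene passed the threshold. Genes of Spermatogonia, the dividing germ cells that precede meiosis, lay higher in 21 of 25 members with a median of 0.28 (camera adjusted p = 0.00491). Cell cycle genes were higher in 17 of 21 (median 0.24), Leydig cell and steroid hormone genes in 13 of 16 (median 0.17), and Heat shock and unfolded protein response genes in 13 of 18 (median 0.24). Adipocyte genes were lower in 9 of 9 (median -0.86). Each of these 5 calls was lost with an estimated correlation (adjusted p = 0.852 for each), and fry called 0 lists. Meiotic chromosome axis and synapsis genes were lower in 22 of 26 members with a median of -0.15, which did not pass (camera adjusted p = 0.124, and 0.933 with an estimated correlation). Meiotic recombination genes had a median of -0.06 with 16 of 31 lower (camera adjusted p = 0.418, and 0.933 with an estimated correlation).

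Named members did not pass (adjusted p = 1, limma). The spermatogonial genes Upp1 and Nanos3 were at 1.22 (SE 0.70) and 1.08 (SE 0.76). Cdk1, the kinase that drives entry into division, was at 0.43 (SE 0.20) and Aurka, a spindle kinase, at 0.40 (SE 0.25). Hsd3b1 and Cyp17a1, enzymes of testosterone synthesis, were at 0.72 (SE 0.43) and 0.29 (SE 0.35), and the heat shock genes Hspb1 and Dnajb1 at 0.47 (SE 0.42) and 0.32 (SE 0.29). Of the axis proteins, Sycp2 was at -0.83 (SE 0.83) and Hormad2 at -0.43 (SE 0.41). Prdm9, which places the sites of meiotic recombination, was at -0.59 (SE 0.44) and Tex15 at -1.01 (SE 0.80). The histone acetyltransferase genes Kat5 and Kat14 were at 0.42 (SE 0.24) and 0.52 (SE 0.31), and the methyltransferase genes Setd1a and Smyd3 at 0.91 (SE 0.55) and -0.55 (SE 0.37). The genes with the smallest p were Vmn1r181, Tspan9, Vps39, Pfkl and Axin2 on the higher side and Ganc, Zfp536, Hpse2, Crybg2 and Atp13a4 on the lower, and 0 of the 10 passed (adjusted p = 1, limma). Vmn1r181, a vomeronasal receptor gene, stood at 127 ± 18.4 against 60.5 ± 1.55 normalised counts, and Crybg2 at 18.6 ± 8.46 against 87.2 ± 34.2 (SD, n = 3 each).

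In all, limma called 0 of 17896 genes in HMS-I1 against Control, and 73 had an unadjusted p under 0.05, again far below the 894.8 expected by chance. With the set as a term it called 0, and of the 5 list calls only the Adipocyte call was kept. Camera then called 4 other lists, with Macrophages (-0.20), Extracellular matrix (-0.27) and Interferon response (-0.31) lower and Cytosolic ribosomal proteins (0.17) higher, and 0 with an estimated correlation (smallest adjusted p = 0.752). The Adipocyte median was -2.13 in the first set and 0.76 in the second, and without Control replicate 1 it was 0.21. That control library had a mean log2 value of 9.36 over the 9 genes, against 6.67 and 4.71 in the other controls, and the call was also lost without HMS-I1 replicate 1 (-0.54). The Spermatogonia median was -0.17 in the first set and 0.03 in the second. Its call was lost without HMS-I1 replicate 3 (0.04), HMS-I1 replicate 2 (0.07), Control replicate 1 (0.11) or Control replicate 2 (0.12). The Cell cycle median was near 0 in the first set and 0.14 in the second, with the call lost without Control replicate 2 (0.13) or HMS-I1 replicate 3 (0.08). The Leydig median was -0.04 and 0.38, with the call lost without Control replicate 3 (0.17), HMS-I1 replicate 2 (0.21) or HMS-I1 replicate 3 (0.09). Heat shock genes were at 0.12 and -0.03, with the call lost without Control replicate 1 (0.11), Control replicate 2 (0.08) or HMS-I1 replicate 2 (0.05).

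In AA against Control, no gene passed the threshold, but more lists stood apart than under MTX or HMS-I1. Extracellular matrix genes, which encode collagens and other scaffold proteins of connective tissue, were higher in AA in 17 of 17 members, with a median of 0.64 (camera adjusted p = 5.53e-06). Interferon response genes were higher in 18 of 20, with a median of 0.68 (camera adjusted p = 5.53e-06). Macrophage and leukocyte genes were higher in 17 of 21 (median 0.51), Leydig cell genes in 14 of 16 (median 0.44) and Endothelium genes in 10 of 11 (median 0.40). Peritubular myoid and smooth muscle genes were higher in 10 of 11 (median 0.36) and Sertoli cell genes in 20 of 24 (median 0.33). Among germ cell lists, Elongating spermatids were lower in 19 of 21 (median -0.31), the piRNA pathway, which silences transposons in the germ line, in 20 of 22 (median -0.17), Meiotic chromosome axis and synapsis genes in 21 of 26 (median -0.14) and Pachytene and late spermatocytes in 15 of 18 (median -0.15). Lists that mark the library sets moved too, with the 13 mitochondrially encoded genes higher in 13 of 13 (median 0.96) and Linker and variant histones lower in 17 of 20 (median -0.42). In all, 17 lists were called, 11 higher and 6 lower, and 0 were called with an estimated correlation, where the smallest adjusted p was 0.436, or by fry. With an estimated correlation the Extracellular matrix and Leydig lists had an adjusted p of 0.439, the Macrophage, Endothelium, Sertoli and Meiotic chromosome axis lists one of 0.462, the myoid list one of 0.524, the Interferon, Elongating spermatid, piRNA, Pachytene and Linker histone lists one of 0.436, and the mitochondrial list one of 0.643.

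The members with the smallest p had values in the direction of their lists and did not pass. Lum, a collagen-binding proteoglycan, was at 0.69 (SE 0.35) and Col5a1, a collagen chain, at 0.41 (SE 0.24). Irf9, an interferon regulatory factor, was at 0.87 (SE 0.34) and Ifih1, a sensor of viral RNA, at 0.96 (SE 0.51). The macrophage receptors Adgre1 and Cx3cr1 were at 0.90 (SE 0.46) and 1.00 (SE 0.69), and the vessel receptors Kdr and Tek at 0.60 (SE 0.28) and 0.50 (SE 0.33). Cyp11a1, which makes the first steroid from cholesterol, was at 0.84 (SE 0.50) and Hsd3b1 at 0.63 (SE 0.43). Prm1, a protamine that packs sperm DNA, was at -1.31 (SE 0.65) and Oaz3, an antizyme of spermatids, at -0.51 (SE 0.25). Pld6 and Piwil4, which act in making piRNA and in guiding it to transposons, were at -0.72 (SE 0.33) and -0.96 (SE 0.47). Ccdc155, which links telomeres to the cytoskeleton in prophase, was at -0.30 (SE 0.19) and Syce2, of the synaptonemal complex, at -0.32 (SE 0.21). Tyms, the thymidylate synthase that folate feeds, was at 1.01 (SE 0.49). The genes with the smallest p were Ptpro, Pkia, Rsad1, Stard5 and Adam12, which lay higher, and Krtcap2, Cenpx, Krt10, Arhgef40 and Pomc, which lay lower, and none passed (adjusted p = 1.00, limma). Pkia, an inhibitor of protein kinase A, stood at 492 ± 78.9 against 255 ± 58.0 normalised counts and Cenpx, a centromere protein, at 306 ± 35.1 against 498 ± 85.9 (SD, n = 3 each).

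Across 17896 genes, limma called 0 in AA against Control, and 143 had an unadjusted p under 0.05, where 894.8 are expected by chance. With array quality weights it called many genes, as given below with the limits of those weights. With the set as a term it called 0, and 8 of the 17 list calls were kept, with smaller medians for Extracellular matrix (0.29), Interferon response (0.43) and Elongating spermatids (-0.20). The Extracellular matrix call was lost with the set and a replicate block together (0.16, camera adjusted p = 0.0952). The mitochondrial (-0.33) and Linker histone (-0.04) calls were lost with the set term. The myoid (-0.08) and Sertoli (-0.01) calls were lost with the set term as well, and also without Control replicate 1 (0.24 and 0.21), Control replicate 2 (0.01 and 0.19), AA replicate 2 (0.26 and 0.25) or AA replicate 3 (0.13 and 0.08). Their medians were 0.01 and -0.01 within the first set and -0.07 and 0.09 within the second. The mitochondrial and Linker histone medians were -0.16 and -0.04 within the first set and -0.56 and -0.02 within the second. These 2 calls were lost without Control replicate 1 (0.24 and -0.28) or AA replicate 2 (0.38 and -0.25), and the mitochondrial call without Control replicate 2 (0.25) or AA replicate 3 (0.28). Within the first and second set, the medians were 0.23 and 0.49 for Extracellular matrix, 0.05 and 1.10 for Interferon response, and -0.11 and -0.39 for Elongating spermatids. The Extracellular matrix and Interferon calls were kept whichever of the 6 libraries was left out, with medians of 0.33 to 0.85 and 0.31 to 1.13. With array quality weights, however, the Interferon call was lost. The other 15 calls were each lost without at least 1 library, those of Elongating spermatids (-0.12) and Macrophages (0.10) without AA replicate 3, and those of the Leydig (0.44) and piRNA (-0.12) lists without Control replicate 3. Macrophage genes had a median of -0.14 in the first set and 0.61 in the second, Leydig genes 0.03 and 0.57, piRNA genes -0.06 and -0.23, Endothelium genes -0.07 and 0.31, Meiotic chromosome axis genes 0.04 and -0.44 and Pachytene genes 0.03 and -0.32. Mean log2 values of the Extracellular matrix list were 10.09, 10.66 and 11.07 in the AA libraries and 10.17, 9.53 and 10.30 in the controls.

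In TSA against Control, genes of Round spermatids, the first haploid germ cells, were lower in 21 of 22 members with a median of -1.22 (camera adjusted p = 1.09e-08). The low values lay in TSA replicates 2 and 3, with means over the list of 10.32 and 11.17 on the log2 scale. TSA replicate 1, at 12.41, resembled the controls at 12.18, 12.50 and 12.16. Elongating spermatids were lower in 18 of 21 (median -0.31) and Adipocyte genes in 9 of 9 (median -1.64). Spermatogonia genes were higher in 24 of 25 (median 0.41), Sertoli cell genes in 21 of 24 (median 0.37), Leydig cell genes in 16 of 16 (median 0.35), Cell cycle genes in 17 of 21 (median 0.26) and Folate and one-carbon metabolism genes in 19 of 21 (median 0.32). Each of these 8 calls was lost with an estimated correlation (adjusted p = 0.537 for each), and fry called 0 lists. Meiotic chromosome axis and synapsis genes had a median of -0.16 with 16 of 26 lower, and Meiotic recombination genes one of 0.05 with 14 of 31 lower, and neither list passed (camera adjusted p = 0.711 and 0.943, and 0.903 and 0.968 with an estimated correlation).

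**Figure D2:**
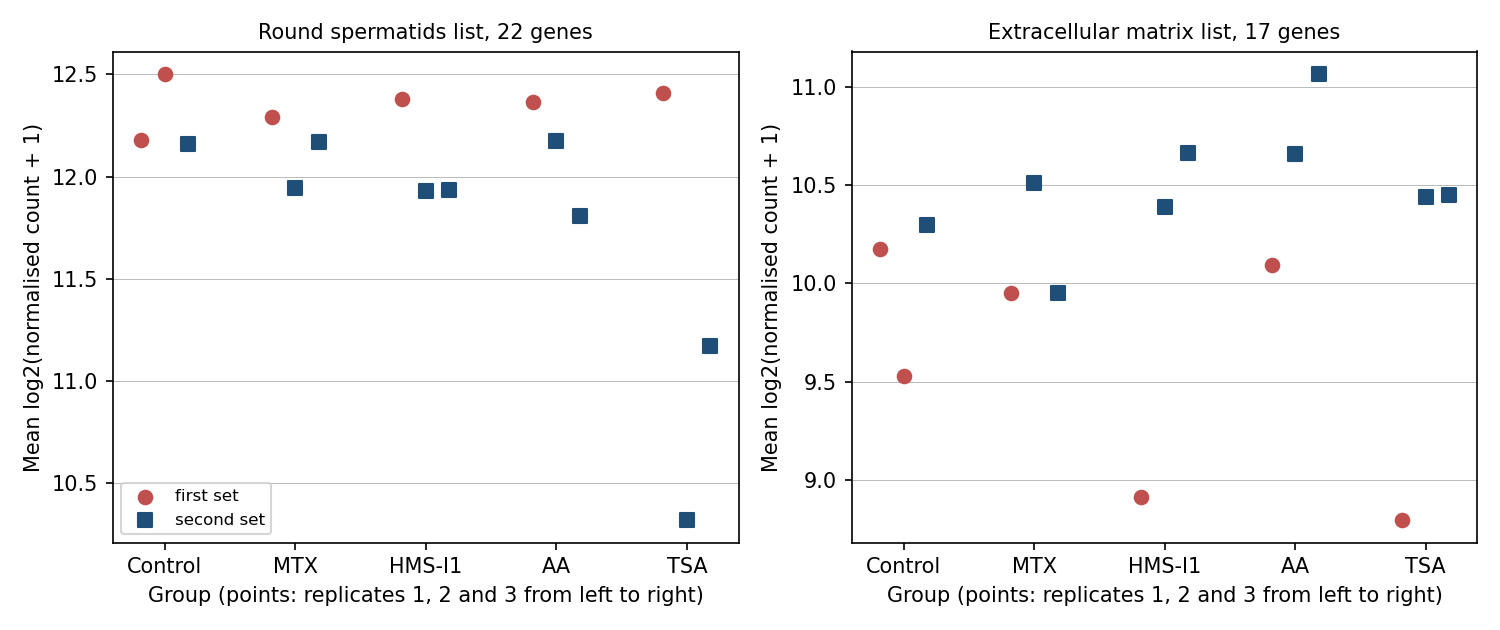
Mean log2(normalised count + 1) of the 22 Round spermatid genes (left) and the 17 Extracellular matrix genes (right) in each of the 15 libraries, by group, with 1 point per library and no error bar. Circles mark the first set and squares the second. TSA replicates 2 and 3 lie at 10.32 and 11.17 in the left panel, below the other 7 libraries of the second set at 11.81 to 12.17.

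With all 15 libraries, no single gene passed in TSA against Control, and the members named here are values only. Sun5, which couples the sperm tail to the head, was at -1.51 (SE 0.48) and Acrv1, an acrosomal protein, at -1.44 (SE 0.47). Tnp2 was at -1.27 (SE 0.43) and Akap3, of the sperm tail sheath, at -1.58 (SE 0.59). Calr3, a chaperone of germ cells, was at -2.11 (SE 0.72) and Spag6, of the sperm axoneme, at -0.83 (SE 0.37). Cdyl, a chromodomain protein of spermatids listed with the acetyltransferases, was at -1.69 (SE 0.52), while Kat14 was at 0.73 (SE 0.31). The histone methyltransferase genes Suv39h2 and Suv39h1 were at -0.68 (SE 0.30) and 0.60 (SE 0.28). Lin28a and Kit, which mark early and differentiating spermatogonia, were at 0.96 (SE 0.52) and 0.60 (SE 0.38), the Sertoli genes Fshr and Clu at 0.78 (SE 0.58) and 0.56 (SE 0.42), and Hsd3b1 and Cyp17a1 at 0.71 (SE 0.43) and 0.52 (SE 0.35). The folate genes Mthfd1l and Folr1 were at 0.81 (SE 0.41) and 0.53 (SE 0.28), and the fat cell genes Adipoq and Fabp4 at -2.56 (SE 1.04) and -3.37 (SE 1.44). The genes with the smallest p were Stard5, Ptpro, Cyp2d22, Cldn12 and Klhl18 on the higher side and Tmem86b, Adora3, Cldn34c1, Vwa5b1 and Adamts20 on the lower, all with an adjusted p of 0.848 (limma). Tmem86b stood at 56.6 ± 24.7 in TSA and 149 ± 1.64 normalised counts in Control (SD, n = 3 each), a difference of -1.46 (SE 0.32).

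The count for TSA against Control rested on 1 library. With all 15 libraries limma called 0 of 17896 genes, and 1027 had an unadjusted p under 0.05, 954 of them lower in TSA. Without TSA replicate 1 it called 992 genes, of which 991 fell and 1 rose, and the remaining TSA libraries are then both of the second set. With the set as a term as well, a fit chosen after seeing the data, it called 1009, of which 1007 fell and 2 rose, and 866 genes were called in both fits. With the set as a term and all libraries it called 0, with a smallest adjusted p of 0.590. With array quality weights and all libraries it called many genes, as given below with the limits of those weights.

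Without TSA replicate 1, the library that resembled the controls was left out, and TSA rested on replicates 2 and 3 alone. With all libraries no gene passed. In this smaller fit 991 of all 17896 genes fell. Of the 22 Round spermatid genes 9 fell (adjusted over all genes), and 9 also with the set as a term. Sun5 fell, at -2.18 (SE 0.34, adjusted p = 0.00490, limma), and so did Acrv1, at -2.10 (SE 0.35, adjusted p = 0.00544). Elongating spermatids had 2 of 21 members lower past the threshold and Pachytene and late spermatocytes 2 of 18, with Tnp2 at -1.85 (SE 0.34), Akap3 at -2.43 (SE 0.42), Calr3 at -3.13 (SE 0.52) and Spag6 at -1.32 (SE 0.29). Cdyl fell as well, at -2.43 (SE 0.37, adjusted p = 0.00490). Meiotic chromosome axis and synapsis genes had 0 of 26 past the threshold and Spermatogonia 0 of 25. No test compared these counts between lists or with the share over all genes. Genes chosen after their values were seen, as large falls called in both fits, include Cst13, a cystatin, at -4.60 (SE 0.97), Pfn3, a profilin of germ cells, at -4.60 (SE 1.06), Cypt15 at -4.45 (SE 0.92), Ccdc185 at -4.29 (SE 0.75) and Iqcf6 at -4.29 (SE 0.79). With the set as a term as well these falls were smaller, at -3.92, -3.21, -3.30, -3.93 and -3.74 in the same order.

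Of the 8 list calls with all libraries, 7 were kept with the set as a term, where camera also called Extracellular matrix lower (-0.47) and Histone lysine demethylases higher (0.13), and 0 lists with an estimated correlation (smallest adjusted p = 0.618). The calls of Round spermatids, Spermatogonia and Folate and one-carbon metabolism were kept whichever of the 6 libraries was left out. The Round spermatid median was -0.79 with the set as a term, -1.32 within the second set and 0.09 within the first, and it ran from -1.71 to -0.50 when 1 library was left out. The Elongating spermatid median was -0.72 and 0.03, and its call was lost without TSA replicate 2 (-0.27). The Adipocyte median was 0.24 within the second set and -2.19 within the first, and its call was lost without Control replicate 1 (-0.39) or TSA replicate 1 (-2.26). The Spermatogonia median was 0.31 within the second set and 0.07 within the first, and that of the Folate list 0.45 and 0.06. The Leydig median was 0.79 and -0.13, with the call lost without Control replicate 3 (0.34) or TSA replicate 3 (0.13). Sertoli genes were at 0.25 and -0.00126, with the call lost without TSA replicate 2 (0.26) or TSA replicate 3 (0.18), and Cell cycle genes at 0.20 and 0.07, with the call lost without TSA replicate 3 (0.13). Rescaling to equal totals or by quantiles moved the median of all genes in this comparison from 0.01 to 0.11 or 0.12. The Elongating spermatid median then shrank to -0.21 or -0.17, and none of the 8 lists changed direction or lost its call.

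Direct comparisons of the treatments asked whether any of them differed from another. In all 6 pairs limma called 0 genes with all 15 libraries. The genes with an unadjusted p under 0.05 numbered 109 for HMS-I1 against MTX, 304 for AA against MTX, 894 for TSA against MTX, 223 for AA against HMS-I1, 485 for TSA against HMS-I1 and 741 for TSA against AA. The F-test of any difference among the 5 groups also called 0, with 230 genes at an unadjusted p under 0.05. Without TSA replicate 1, TSA differed from MTX in 767 genes, from HMS-I1 in 537 and from AA in 616, and the F-test called 246. Leaving out HMS-I1 replicate 3 gave 1 gene for HMS-I1 against MTX and 1 by the F-test, and leaving out Control replicate 1 gave 1 by the F-test. Array quality weights with all libraries gave many genes for TSA against AA and by the F-test, as given below.

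Round spermatid genes were lower in TSA than in each other treatment, by a median of -0.97 against MTX, -0.85 against HMS-I1 and -0.84 against AA, with 20 of 22 members lower each time (camera adjusted p = 4.56e-08, 6.90e-11 and 1.23e-07). Adjusted over the list alone, 2 members were lower than in MTX. With an estimated correlation the adjusted p was 0.636, 0.737 and 0.602. Within the second set the medians were -1.54, -1.35 and -1.33, and within the first 0.11, 0.05 and 0.04. Extracellular matrix genes were higher in AA than in HMS-I1 in 17 of 17 members (median 0.68) and lower in TSA than in AA in 17 of 17 (median -0.72). With an estimated correlation their adjusted p was 0.614 and 0.790, and the medians were 1.11 and -1.36 within the first set and 0.28 and -0.36 within the second. Interferon response genes were lower in HMS-I1 than in MTX in 18 of 20 (median -0.51) and higher in AA than in HMS-I1 in 19 of 20 (median 0.64). Their adjusted p with an estimated correlation was 0.974 and 0.431, and the medians were -0.34 and 0.48 within the first set and -0.45 and 0.80 within the second. Pachytene and late spermatocyte genes were lower in AA than in MTX in 16 of 18 (median -0.24), with an adjusted p of 0.179 with an estimated correlation and medians of -0.08 and -0.35 within the sets.

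The 4 treatments share the 3 control libraries, so their fold changes resemble each other by chance. The correlation of log2 fold changes across the 17896 genes, which are not independent replicates, averaged 0.587 over the 6 pairs of treatments. Unchanged groups simulated against the same controls gave 0.4996, and 0.678 when the library sets were kept. The covariance averaged 0.182 and was below the simulated 0.250, or 0.263 with the sets. With the set as a term the correlation was 0.361 against a simulated 0.523. Both averages lay below those simulated with shared controls and library sets, and so show no similarity beyond these. The 3 controls cannot be split into 2 groups of at least 2 libraries, so the part that comes from sharing them was not measured directly. The mean correlation was 0.819 without Control replicate 3 and 0.485 without Control replicate 2. No simulated value was computed for fits with fewer controls, so these 2 cannot be set against those above.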

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

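The library set as a term, fits within a set, array weights with the set term, and the set term without TSA replicate 1 were chosen after seeing the data, as was leaving out libraries for the pairs of treatments and the F-test. The counts of 0 genes stayed at 0 under other pseudocounts, filters, scalings, variance models and a fold threshold. Of 58 list results, 58 kept their direction and side of the threshold with a pseudocount of 0.5, 56 with 5, 45 without a filter, 50 with rescaling to equal totals, 50 with quantiles and 56 without a variance trend. For every change given here the cause was not tested. With 3 libraries per group that mix both sets, most simulated changes of 1 on the log2 scale were missed, the depth is unknown, and a count test was not run because whole reads are not recoverable.

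Without a filter, all 5 MTX calls were lost, among them Interferon response (0.31) and Mitochondrially encoded genes (1.12). So were the HMS-I1 calls of Leydig cells and Heat shock and the AA calls of Meiotic chromosome axis, Pachytene, Peritubular myoid, Mitochondrially encoded and ribosomal genes. With quantiles, the AA call of Elongating spermatids (-0.13) was lost, with those of Meiotic chromosome axis, Pachytene, piRNA pathway and ribosomal genes in AA and of Leydig cells and Heat shock in HMS-I1. A fit of only the 6 libraries of the 2 groups called 1 gene for MTX, 2 for AA and 1 for TSA against Control.

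With the replicate block, taking equal replicate numbers as paired, 0 genes were called in each comparison, and 57 of the 58 list results were the same. Whether the numbers pair the libraries was not settled. Of 30 pairs with the same number, 26 had a correlation over 0.1, with a lowest of -0.58, and 11 of 15 libraries were closest to their own number. These correlations were taken without the set term. Replicate 1 of every group lies in the first set, and Control replicate 2 is the only replicate 2 there. The check therefore cannot tell pairing from the library sets. With the library set and the replicate block together, the medians were -0.52 for Mitochondrially encoded genes and 0.44 for Interferon response (still called) in MTX, 0.0580 for Spermatogonia in HMS-I1, and in AA -0.12 for Peritubular myoid and smooth muscle, 0.16 for Extracellular matrix (call lost), -0.72 for Mitochondrially encoded genes and 0.21 for Cytosolic ribosomal proteins.

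Array weights gave the largest counts, 6645 genes for AA against Control, 4234 for TSA against Control, 3092 for TSA against AA and 5640 by the F-test. AA replicate 2 had a weight of 38.8 and TSA replicate 1 one of 0.230, whose part in these counts was not tested, and the estimate of the weights stopped before it converged. Of the list calls, 8 were lost, those of Elongating spermatids (-0.32), Interferon response (0.58), Meiotic chromosome axis, Pachytene, Leydig cells, Cholesterol biosynthesis and Folate metabolism in AA and of Leydig cells in HMS-I1. Other medians grew, to 0.59 for Spermatogonia and -2.40 for Adipocytes in HMS-I1 and 1.93 for Mitochondrially encoded genes in MTX. The counts of list members that follow come from fits that called 6645 of all 17896 genes for AA and 4234 for TSA. They were not tested against these shares and are no result about the lists. Under these weights, the calls of members past the threshold, summed over the 4 treatments so that a gene can count more than once, numbered 20 for Spermatogonia, 10 for Meiotic chromosome axis and synapsis, 13 for Meiotic recombination, 13 for Pachytene and late spermatocytes, 19 for Round spermatids and 17 for Elongating spermatids. They numbered 20 for Sertoli cells, 10 for Leydig cells and steroidogenesis, 9 for Peritubular myoid and smooth muscle, 14 for Macrophages and other leukocytes, 10 for Endothelium, 1 for Erythroid cells, 2 for Epididymis, 6 for Adipocytes, 7 for Extracellular matrix and 9 for Y-linked genes. For chromatin they were 17 for Histone lysine methyltransferases, 8 for Histone lysine demethylases, 9 for Histone acetyltransferases, 8 for Histone deacetylases and 24 for Linker and variant histones. The other lists had 11 for p53 and DNA damage response, 13 for Interferon response, 10 for Immediate early genes, 10 for Heat shock and unfolded protein response, 11 for piRNA pathway, 20 for Cholesterol biosynthesis, 18 for Folate and one-carbon metabolism, 7 for Cell cycle, 11 for Mitochondrially encoded genes and 18 for Cytosolic ribosomal proteins.

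With the library set as a term, 38 of the 58 list results were the same. The medians were 0.19 for Interferon response and -0.0145 for Mitochondrially encoded genes in MTX, 0.000377 for Spermatogonia in HMS-I1, and -0.0778 for Peritubular myoid and smooth muscle and -0.33 for Mitochondrially encoded genes in AA. The mean correlation between treatments was 0.361. With array weights as well, limma called 95 genes for MTX against Control, 922 for HMS-I1 against MTX, 1 for AA against MTX and 5 by the F-test. The medians were then 0.11 for Interferon response and -0.25 for Mitochondrially encoded genes in MTX, -0.0640 for Spermatogonia in HMS-I1 and -0.40 for Mitochondrially encoded genes in AA. With the set term and without TSA replicate 1, limma called 1009 genes for TSA against Control, 1322 against MTX, 1011 against HMS-I1, 1108 against AA and 603 by the F-test.

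Within the 9 libraries of the second set, limma called 7 genes for TSA against Control, 2 for HMS-I1 against MTX, 3 for AA against MTX, 4 for TSA against MTX, 7 for TSA against HMS-I1, 6 for TSA against AA and 6 by the F-test. The lone control library is assumed there to vary like the other groups, and the set is itself uneven on the second principal component. Medians were -0.0720 for Mitochondrially encoded genes in MTX, 0.0259 for Spermatogonia and 0.76 for Adipocytes in HMS-I1, -0.0674 for Peritubular myoid and smooth muscle and -0.56 for Mitochondrially encoded genes in AA, and 0.24 for Adipocytes in TSA. Within the 6 libraries of the first set, with 1 library per treatment, limma called 1 gene for MTX against Control, where the spread comes from the 2 control libraries alone. The medians in MTX were -0.00499 for Macrophages, -0.35 for Interferon response and -0.19 for Mitochondrially encoded genes, and in HMS-I1 -0.17 for Spermatogonia and -0.0407 for Leydig cells. In AA they were 0.0357 for Meiotic chromosome axis, 0.0272 for Pachytene, -0.11 for Elongating spermatids, -0.0103 for Sertoli cells, -0.14 for Macrophages, 0.23 for Extracellular matrix, 0.0452 for Interferon response and -0.16 for Mitochondrially encoded genes. In TSA they were 0.0888 for Round spermatids, 0.0292 for Elongating spermatids, -0.00126 for Sertoli cells and -0.13 for Leydig cells.

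Leaving out each library in turn gave 0 to 1 genes for MTX, HMS-I1 and AA against Control, with the 1 gene without Control replicate 1. It gave 0 to 992 for TSA against Control, 0 to 767 for TSA against MTX, 0 to 537 for TSA against HMS-I1, 0 to 616 for TSA against AA and 0 to 246 by the F-test, each highest without TSA replicate 1, and 0 to 1 for HMS-I1 against MTX. The medians in MTX ran from -0.0797 to 1.09 for Erythroid cells, -0.0161 to 0.70 for Interferon response and -0.21 to 2.56 for Mitochondrially encoded genes. In HMS-I1 they ran from 0.0421 to 0.63 for Spermatogonia and -2.03 to 0.21 for Adipocytes, and for Elongating spermatids from -0.53 to -0.12 in AA and -0.53 to -0.27 in TSA. The mean correlation between treatments ran from 0.485 to 0.819. Of 116 gene values named by the rule, 54 passed with array weights, 4 with the set term and array weights (Rsad1, Rnf182, Vangl1 and Trim6 in MTX), 13 of the 32 in TSA without TSA replicate 1, and none under the alternative scalings. The sign of 19 of the 116 turned under at least 1 alternative, 12 of them within the first set. Over the alternatives, Calr3 ran from -3.46 to 0.11 and Acrv1 from -2.46 to 0.0570 in TSA, Adgre1 from -0.27 to 1.57 in AA, and Sycp2 from -1.41 to 0.20 and Upp1 from 0.19 to 2.59 in HMS-I1.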

Other observations

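The tests for the spermatid values in TSA, for the cell mixtures and depth, for the share of zeros in a set and for other groupings were chosen only after the results were seen. Those for poly(A) tails and shared copies were written down before their values were seen.

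Histone genes led the genes that set the first set of libraries apart. Hist1h2ba, a histone of germ cells, stood at 18713 to 36423 normalised counts in the first set and at 41.9 to 96.3 in the second. Hist1h1a stood at 7442 to 10653 against 11.9 to 41.1, and Hist1h2aa at 9266 to 14942 against 12.2 to 24.8. In the other direction, mt-Co2 ran from 3963 to 69501 in the first set and from 97008 to 639244 in the second. Ssty1, a gene of the Y chromosome, was 0 in the first set and 57.5 to 319 in the second. All its sampled 31-base words (100%) are shared with another gene, so its zeros may come from read assignment between copies. Of the 12 Y-linked genes, 10 were higher in the first set (median 0.30). The single genes named here were chosen after their values were seen.

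Several explanations of the library sets were tested. The test for transcripts without a poly(A) tail kept in the 6 libraries was void, since 0 of the listed non-coding RNA genes were tested. It did not cover the replication-dependent histone genes, which were high in these libraries, so this explanation remains open. For another mixture of cell types, 0% of the 45 genes differing by over 7 belonged to the cell type lists, which decides nothing where 0.460 were expected (one-sided exact binomial p = 0.630). The listed cell types are argued against as the source of those 45 genes. The largest median difference of a cell type list was 1.12 in size, with an SE of 0.25. That SE is taken over the 11 genes of the list, which may vary together, and not over libraries. A mixture remains open for the smaller differences. A lower depth of the 6 libraries is argued against only as the source of large differences in genes with high means. Of these genes, 2.40% (145 of 6046) differed by over 2. Depth, which is unknown, remains open for the smaller differences. Each group has libraries in both sets, so no effect of a treatment was weighed.

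The spermatid lists were lower in TSA replicates 2 and 3. Membership of the second set alone is argued against for the Round spermatid list. Both libraries lay below the other 7 of their set (11.81 to 12.17), by at least 0.638 where the SD of those libraries was 0.148. These low values prompted the test, and it treats the set as 2 levels. On the first principal component, which defines the sets, TSA replicate 2 lay furthest out in the second set, at 116. TSA replicate 3 lay at 71.3, close to AA replicate 3 at 71.8, whose mean of 11.81 was the lowest of the 7. A link of the spermatid values with that component remains open. A smaller share of spermatids remains open, with 6 of the 7 other cell type lists above 0. Pachytene was at -0.03, with an SE of 0.21 over the 18 genes of the list. An effect of the treatment remains open too, since TSA replicate 1 lay 0.0696 above the mean of the 2 control libraries of its set, a single library.

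A further 226 genes were at 0 in several libraries and well expressed in others. The median share of 31-base words in common with another gene was 100% for the 225 with a value and 0.446% for other tested genes, so reads shared between near-identical copies may account for many of them. The library set remains open, since the zeros of 34.1% of these genes (77) lay in 1 set. No biological explanation was tested.

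Other groupings of the same libraries were run as well. Since every real count was 0, all groupings give as many genes by construction (10 of the 10 splits of each pair of groups, the real one included), and the counts cannot test chance. The highest other counts were 0 for MTX, 0 for HMS-I1, 2 for AA and 1778 for TSA against Control, 1 for HMS-I1 against MTX, 2 for AA against MTX, 0 for TSA against MTX, 0 for AA against HMS-I1, 395 for TSA against HMS-I1 and 0 for TSA against AA. The splits with 1778 and with 2 genes against Control put replicate 1 of the treatment with Control replicates 1 and 2, which is the library set, and so point to sample structure. With the set as a term the real grouping gave 0. For the F-test the same holds (100 of 100 regroupings, the real one included), with a highest other count of 378. The Round spermatid median of -1.22 in TSA was reached in size by 2 of the 10 splits, the real one included (highest other 1.31), and the Extracellular matrix median of 0.64 in AA by 3 of the 10 (highest other 0.71). With 10 splits the share cannot lie under 0.05.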
